A study of Mus musculus with 8 samples.

How the data were processed

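RNA (100 ng) from 8 clonal mouse lines grown in DMEM with 10% fetal calf serum was labelled with the WT PLUS kit and hybridised to Affymetrix arrays, 1 array per line. The lines come from tumours driven by Myc and activated Nras, 4 of them ICC and 4 HCC, with 2 female- and 2 male-labelled lines in each type. Replicate numbers 1 to 4 follow the order of the samples and are ICC9, ICC10, ICC2.7 and ICC2.9 in one type and HCC1, HCC4, HCC2.1 and HCC2.4 in the other.

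The deposited table holds log2 values with 2 decimals, which per the submitters' processing notes were made by RMA in the oligo package. The versions of RMA, oligo and the annotation are not given in the sources used here. The table has 39993 probe sets and 0 missing values. Of the probe sets, 23521 name exactly 1 gene, 1814 name several and 14658 name none here. All 23328 single-gene probe sets with an identifier in the RefSeq table carried the same symbol there. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 22180 genes, 1082 of them chosen from more than 1 probe set. No filter on dim probe sets was applied. Scanner files were not used here, so signal over background was not assessed, and the number of arrays limits the precision.

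Differences between ICC and HCC lines were tested on log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over genes, adjusted p under 0.05). No covariate was used, since sex is balanced over the types. The fit had 6 residual and 2.85 prior degrees of freedom. Differences between female- and male-labelled lines were tested with tumour type in the model, and the interaction of type and sex with both. An SE is the moderated standard error of limma, and values after ± are standard deviations over lines. Distances between lines are mean absolute log2 differences over genes and were not tested.

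Of 32 gene lists written before the data were examined, 29 with at least 5 measured genes were tested with camera (preset correlation 0.01 between genes, two-sided, Benjamini-Hochberg over lists), again with a correlation estimated per list, and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move on balance one way, or in its mixed form in either direction, and compares with no other genes. Members were counted when called over all genes and when adjusted over the list alone. The study regulators, the oncogenes of the vector and the sex-linked genes had fewer measured members and are given gene by gene.

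The comparisons, tests, lists, alternatives and rule for naming genes were set before the data were examined. The rule names the 12 largest differences in each direction among called genes without overlap between types, leaving out predicted genes, RIKEN clones, small RNAs and pseudogenes. It also names up to 4 called members per list, or the 2 with the smallest p where fewer than 2 are called, up to 6 genes with the smallest adjusted p for the sex and interaction tests, and a set of fixed marker genes. Of the fixed genes Spp1, Trp53 and Ddx3y were not analysed here because no probe set names them alone, and 1 other is not reported here. Me1 in the report and the genes of the sex lists in the closing section lie outside the rule and were chosen after their values were seen.

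The alternatives set beforehand were eBayes with trend and robust settings, genes above the median level only, quantile normalization or median centring on top of the deposited values, array weights, the mean of a gene's probe sets, a random block or averaging for lines of one type and sex, sex as a covariate, one sex only, leaving out each line, all probe sets, and a larger size threshold. The 8 columns were then found to span only 7 directions. Added after seeing the data were models with the missing direction, with sex and that direction, and without ICC9 with sex in the model, as well as list tests on the sex and interaction terms, a random block and averaging of lines in the sex comparison, and distances over probe sets with no gene name.

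The fit was tested on simulated data of 22180 genes with 200 changed, in 20 runs. With 8 independent arrays 5.57% of calls were false, and 75.4% of changes of 1 log2 unit and 96.9% of changes of 2 were recovered. With 1 direction removed 16.06% of calls were false, and 5.64% when the model counted that direction; with type and sex in the model the shares were 17.82% and 4.46%. In 50 runs of 30 simulated lists, 100% of lists shifted by 0.5 were called, with 0.04 unshifted lists called per run. Simulated genes were drawn independently, while the correlation estimated for the cell cycle list was 0.790. The rate of 0.04 therefore does not cover lists of correlated genes. Simulated lines were also independent, while lines of one type and sex had a consensus correlation of 0.398, which the simulated shares of false calls leave out. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the block and array weight fits used statmod 1.5.0.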

Results

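Expression was measured in 8 clonal mouse lines grown from liver tumours, 4 from intrahepatic cholangiocarcinoma (ICC, a cancer with bile duct features) and 4 from hepatocellular carcinoma (HCC, a cancer with hepatocyte features). Tumours of both types were driven by Myc together with an activated Nras, carried on 1 vector, in mice of the C57BL/6 strain. Hepatocytes were the transformed cells, so the comparison asks which genes differ between lines of the 2 cancer types when the cell of origin and the oncogenes are shared. ICC arose after focal electroporation of the liver and HCC after hydrodynamic tail-vein injection, so tumour type and delivery method cannot be separated in these lines. ICC9 and ICC10 are labelled female, ICC2.7 and ICC2.9 male, HCC1 and HCC4 male, and HCC2.1 and HCC2.4 female, in the order of replicates 1 to 4 of each type. Each line was cultured without treatment and hybridised to 1 Affymetrix array, and the median log2 signal per array lay between 5.02 and 5.09. The number of arrays, 4 per type, limits the precision of every difference. The labels do not say whether lines share an animal or tumour, so the p-values measure only the spread between these lines.

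Over genes with a name, each line but HCC1 resembled the other line of its own type and sex most. Over probe sets with no gene name 6 of the 8 lines lay nearer to another line, ICC9 or ICC10. HCC1 lay marginally nearer to ICC10 (mean absolute log2 difference 0.262) than to HCC4 (0.264). Among genes above the median level HCC1 was nearest to HCC4 (0.277). Over 22180 genes the mean absolute log2 difference was 0.195 in the 4 pairs of lines of one type and one sex, 0.296 in the 8 pairs of one type and different sex, and 0.300 in the 16 pairs of different types. The closest pair was ICC9 and ICC10, with a mean absolute difference of 0.126 and a Pearson correlation across genes of 0.997, where genes are not independent replicates. The values of the 8 lines span only 7 directions, so each line is a weighted sum of the other 7 to within rounding, and ICC10 carries the largest weight (0.688) in the sum for ICC9. The missing direction lay close to a term for ICC9 alone, given type and sex (cosine 0.989). Little of the variation of ICC9 on its own is therefore left in the values. Its closeness to ICC10 and to other lines cannot be read as resemblance of the cells alone. Among genes above the median level HCC2.1 and HCC2.4 were the closest pair (0.115, against 0.145 for ICC9 and ICC10). Averaged over all pairs within a type the difference was 0.263 ± 0.063 (SD, 12 pairs), and between types it was 0.300 ± 0.040 (SD, 16 pairs). No test was run on pairs, which share lines.

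**Figure D1:**
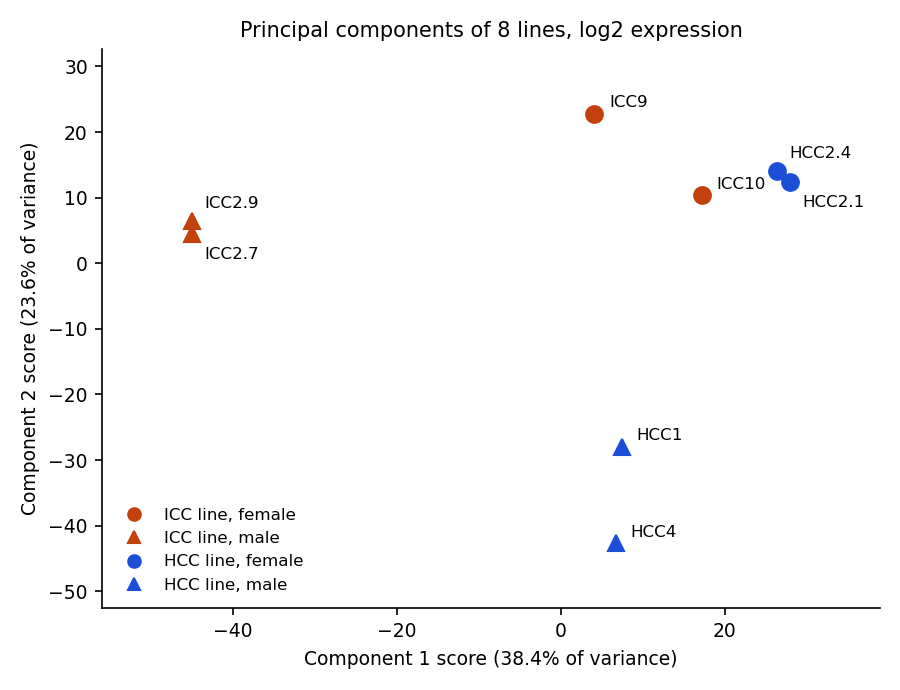
Principal components of the log2 values of 22180 genes in the 8 lines, with the score on component 1 (38.4% of the variance) on the horizontal and on component 2 (23.6%) on the vertical axis; colour gives the tumour type and marker shape the sex label. The male-labelled ICC lines stand apart on component 1 and the male-labelled HCC lines on component 2. On these 2 components ICC10 lies nearer to HCC2.1 and HCC2.4 than to ICC9, although over all 22180 genes ICC9 is its nearest line (0.126).

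Over all 8 lines no test called a difference between the types in 9 markers of hepatocytes, bile duct cells, epithelium and mesenchyme. Albumin, the main secreted protein of hepatocytes, measured 4.32 ± 0.22 log2 units in ICC lines and 4.28 ± 0.14 in HCC lines (SD, n = 4 each). The fetal liver protein Afp stood at 5.43 ± 0.26 and 5.45 ± 0.10. Among bile duct genes, the transcription factor Sox9 measured 11.56 ± 0.11 in ICC and 11.67 ± 0.18 in HCC lines, and Krt7 measured 6.01 ± 0.03 and 5.90 ± 0.06. Krt19 differed widely inside each type (7.88 ± 1.45 in ICC and 7.03 ± 1.18 in HCC, adjusted p = 0.666), as did Cdh1, the epithelial cadherin (5.88 ± 0.52 and 7.21 ± 1.54, adjusted p = 0.416). Hnf4a, a hepatocyte transcription factor, measured 5.51 ± 0.27 and 6.34 ± 0.97 (adjusted p = 0.418), with ICC9 at 5.92 and the other ICC lines at 5.36 to 5.40. Among HCC lines Hnf4a measured 7.26 in HCC2.1 and 7.06 in HCC2.4, but 5.32 in HCC1 and 5.70 in HCC4. Cdh1 measured 8.44 in HCC2.1 and 8.43 in HCC2.4, but 6.73 in HCC1 and 5.23 in HCC4. The epithelial marker Epcam measured 4.48 ± 0.40 and 4.77 ± 0.26, and the mesenchymal filament gene Vim 13.52 ± 0.04 and 13.43 ± 0.04. Alb, Afp and Epcam lay below the median level over all genes (5.66) in both types. Signal over background was not assessed, so a lack of difference in Alb, Afp and Epcam may only reflect low signal. None of these 9 genes passed limma's test over all genes, where the smallest adjusted p of the 9 was 0.416 and 0 of them had an unadjusted p under 0.05. In the female-labelled lines on their own, 2 per type, limma called 3 of the 9: Hnf4a (log2 difference -1.52, adjusted p = 0.0372), Krt19 (1.14, adjusted p = 0.0485) and Cdh1 (-2.17, adjusted p = 0.0192). The spread in that fit comes only from the pairs ICC9 with ICC10 and HCC2.1 with HCC2.4, which lie close (0.126 and 0.178) and may share a source. It called 696 genes, against 58 over all 8 lines, and was not repeated with the missing direction. These 3 calls may therefore be too many.

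**Figure D2:**
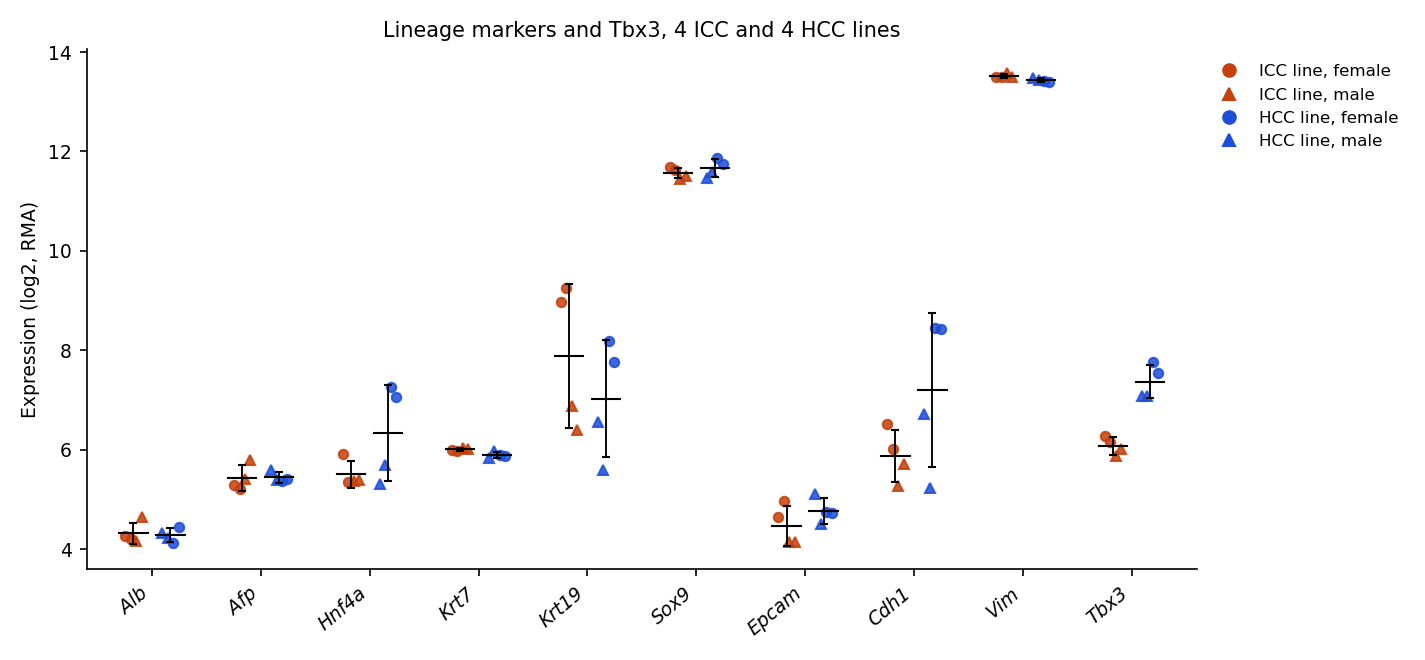
Expression (log2) of 9 hepatocyte, bile duct, epithelial and mesenchymal marker genes and of Tbx3, 1 point per line with the mean and SD of the 4 lines of each type; colour gives the type and marker shape the sex label. The types overlap for Alb, Afp, Krt19 and Cdh1, and Tbx3 is lower in all 4 ICC lines.

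Of 22180 genes tested, 58 differed between ICC and HCC lines, 29 higher in ICC and 29 lower. The gene with the largest rise in ICC lines was Serpinh1, a collagen chaperone of the endoplasmic reticulum, at 10.60 ± 1.06 against 6.23 ± 0.21 (log2, SD, n = 4 each), a 20.7-fold difference. Ptpn13, a tyrosine phosphatase, was 7.70-fold higher (log2 difference 2.95, SE 0.34) and Scara3, a scavenger receptor family member, was 7.43-fold higher (2.89, SE 0.43). The largest fall was in Akr1c18, a steroid dehydrogenase that inactivates progesterone, at 5.09 ± 0.41 in ICC and 9.99 ± 1.22 in HCC lines, a 29.9-fold difference, with HCC1 at 8.16 and the other HCC lines at 10.53 to 10.72. Igfbp3, a carrier of insulin-like growth factors, measured 7.88 ± 0.14 in ICC and 10.78 ± 0.39 in HCC lines (7.44-fold lower, adjusted p = 0.00103). Olr1, a receptor for oxidised low-density lipoprotein, measured 5.91 ± 0.21 and 8.72 ± 0.26 (log2 difference -2.81, SE 0.15, adjusted p = 0.000539) and had the smallest adjusted p of all genes.

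Further single genes were higher in ICC lines. Type III collagen, Col3a1, rose from 5.31 ± 0.36 in HCC to 6.97 ± 0.35 in ICC lines (SD, n = 4 each, adjusted p = 0.0252). The matrix proteoglycan gene Podnl1 was higher by 1.86 log2 units (SE 0.23), the mesenchymal cadherin Cdh11 by 1.39 (SE 0.15) and the adhesion gene Nrcam by 1.30 (SE 0.16), although Nrcam in ICC2.9 reached 5.93 with the other ICC lines at 5.23 to 5.30. The co-stimulatory receptor Cd28 was higher by 1.45 (SE 0.20), with ICC2.7 at 6.00 and the other ICC lines at 6.79 to 6.93. The NADPH oxidase subunit Cyba differed by 1.67, the ciliary gene Evc by 1.30, the exchange factor Def6 by 1.27 and the ubiquitin ligase Wwp1 by 1.20, with adjusted p between 0.01 and 0.035.

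Further single genes were lower in ICC lines. The growth factor gene Igf1 fell by 1.23 log2 units (SE 0.19, adjusted p = 0.0403) and Pdgfb, the B chain of platelet-derived growth factor, fell by 1.46 (SE 0.20, adjusted p = 0.031). The water channel Aqp5 fell by 1.97, the mTOR complex partner Prr5l by 1.54, the phosphodiesterase Pde3b by 1.24 and the protease Ctsw by 1.20 (log2 differences -1.97, -1.54, -1.24 and -1.20). Tmem117, which encodes a membrane protein, fell by 1.48, with ICC2.7 at 6.38 and the other ICC lines at 6.62 to 6.65. The stress gene Gadd45b fell by 1.40 (SE 0.15, adjusted p = 0.014), with HCC4 at 8.86 and the other HCC lines at 8.42 to 8.48. Tbx3, a T-box repressor that the study chose as a regulator from these lines, measured 6.08 ± 0.17 in ICC and 7.37 ± 0.34 in HCC lines (adjusted p = 0.0252). In the list of study regulators, with 1 gene measured, it passed over all genes and adjusted over the list alone, which is not independent evidence of its direction. Limma did not call Tbx3 with the missing direction in the model (adjusted p = 0.0742) or without ICC9 (0.0886). With sex and the missing direction it was called (0.011).

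**Figure D3:**
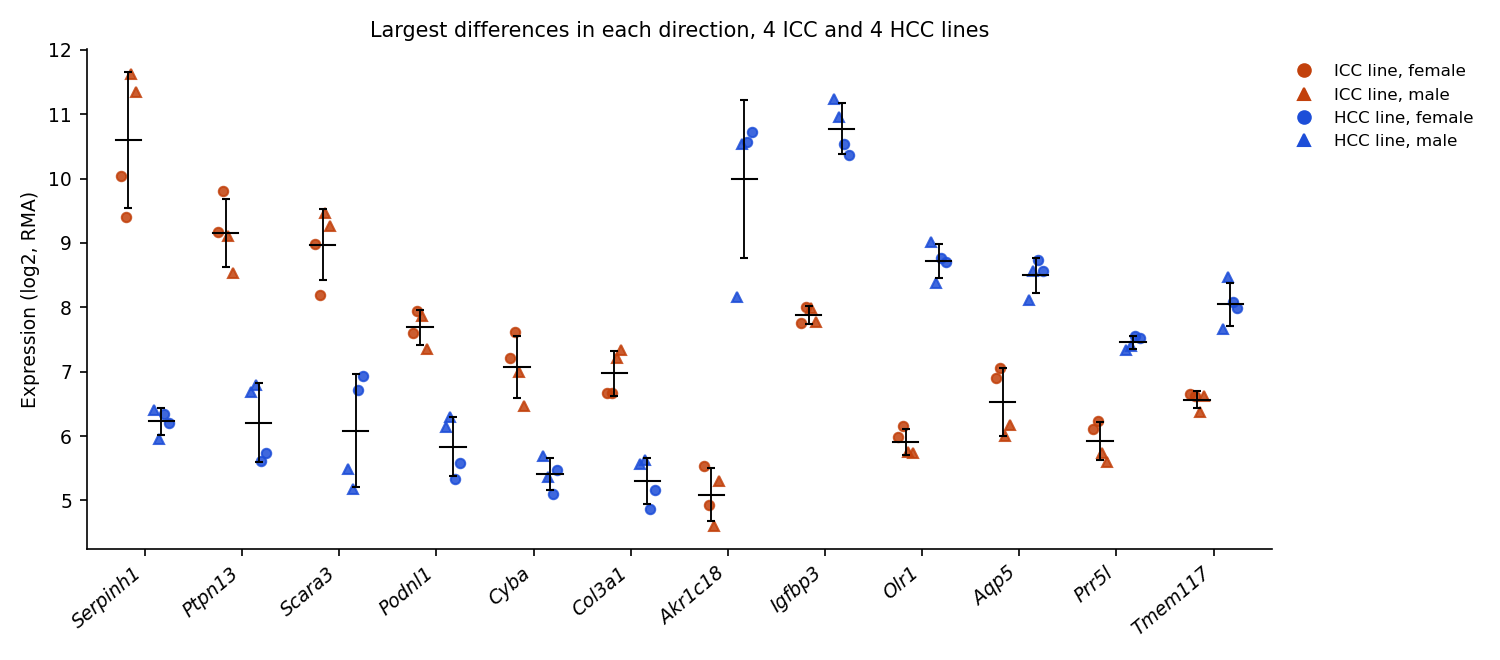
Expression (log2) of the 6 genes with the largest rise and the 6 with the largest fall in ICC lines among those named by size, 1 point per line with the mean and SD of the 4 lines of each type. For each gene all 4 lines of one type lie above all 4 of the other, and HCC1 is the low HCC line for Akr1c18 (8.16).

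All 58 genes separated the 4 ICC from the 4 HCC lines without overlap. Of all genes tested, 1915 (8.60%) separated the types in this way, against 2.86% by chance if the 8 lines were independent. Lines of one type and sex were correlated (consensus correlation 0.398), which raises the share due to chance. The excess over 2.86% therefore does not show a difference between types. An absolute log2 difference of at least 1 was reached by 39 of the 58, 17 higher and 22 lower in ICC. Because the 8 lines span only 7 directions, the arrays held fewer independent values than their number. Counting the missing direction in the model left 12 genes, among them Serpinh1, Akr1c18, Igfbp3, Olr1, Pdx1 and Cdh11. The count was 428 with sex in the model and 119 with sex and the missing direction, 6 with the lines of one type and sex as a random block, and 0 with those lines averaged (limma, 1170 at an unadjusted p under 0.05), and it moved over 1.5 times without ICC9 (2), ICC2.7 (16), ICC2.9 (28), HCC1 (109), HCC4 (91), HCC2.1 (4) or HCC2.4 (5).

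Cell cycle genes were higher in ICC lines as a group. All 28 measured members had a positive difference, with a mean of 0.77 and a median of 0.82 log2 units. Ccnb2, the mitotic cyclin B2, rose from 7.90 ± 0.15 in HCC to 9.06 ± 0.22 in ICC lines (SD, n = 4 each, adjusted p = 0.014) and was the 1 member called over all genes, while 16 rose adjusted over the list alone. The proliferation marker Mki67 differed by 1.25 (SE 0.21, adjusted p = 0.0551) and Cdc20, an activator of the anaphase-promoting complex, by 1.08 (SE 0.19, adjusted p = 0.0609). With camera and a preset correlation between genes the list differed from all other genes (adjusted p = 2.44e-16). With an estimated correlation, 0.790 for this list, the call was lost (adjusted p = 0.861), and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, gave an adjusted p of 0.275. By line the list mean was 9.54 in ICC2.9, 9.43 in ICC2.7, 8.94 in ICC9, 8.89 in ICC10, 8.98 in HCC1, 8.40 in HCC2.4, 8.27 in HCC2.1 and 8.09 in HCC4, so HCC1 lay above ICC9 and ICC10.

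**Figure D4:**
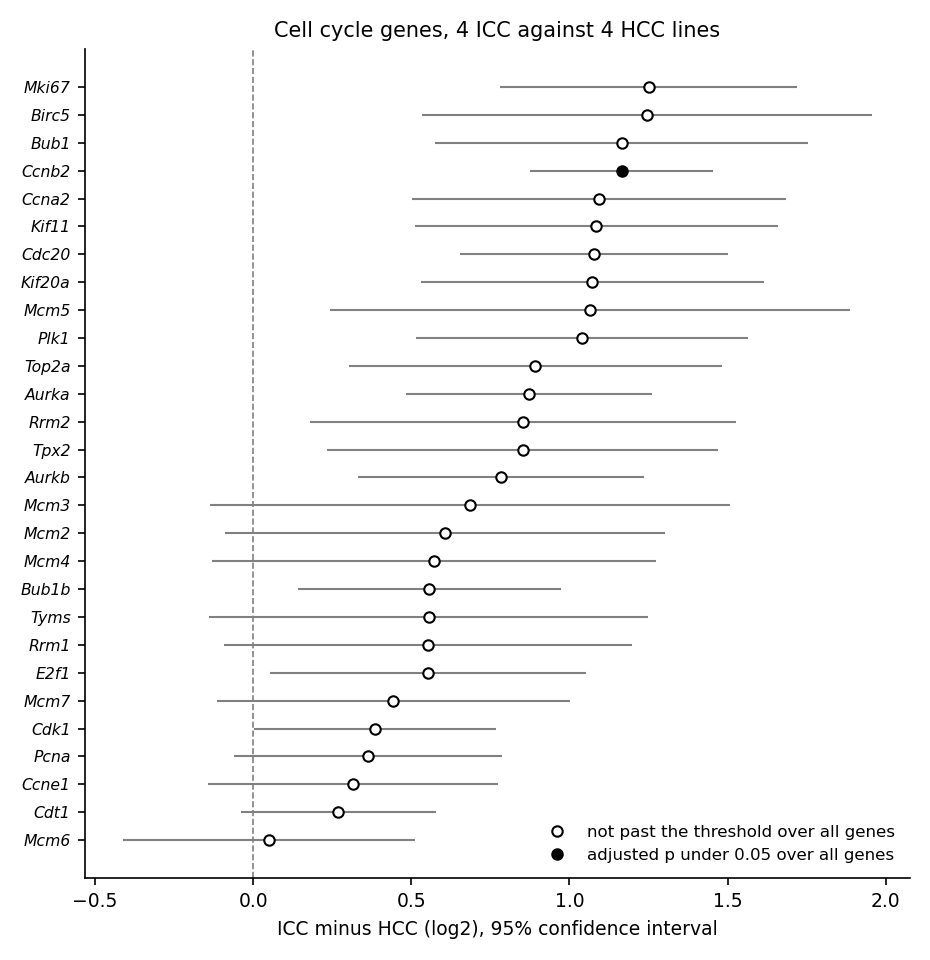
Difference between the 4 ICC and 4 HCC lines (log2, horizontal axis) for each of the 28 measured cell cycle genes, with 95% confidence intervals. All 28 points lie above 0, and the filled point, Ccnb2, is the gene with an adjusted p under 0.05 over all genes.

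Cholesterol and fatty acid synthesis genes were lower in ICC lines as a group. Of 16 measured members 14 had a negative difference, with a mean of -0.19 and a median of -0.29 log2 units, and camera with the preset correlation gave an adjusted p of 0.00309. The call was lost with an estimated correlation (adjusted p = 0.861) and with fry (adjusted p = 0.275). Limma called 0 of the 16 over all genes (9 had an unadjusted p under 0.05), and adjusted over the list alone 6 fell and 1 rose. Hmgcs1, which makes the precursor of mevalonate, differed by -0.52 (SE 0.11, adjusted p = 0.0916), with ICC2.9 at 9.62 and the other ICC lines at 9.84 to 9.87, and Cyp51, which demethylates lanosterol, by -0.56 (SE 0.13, adjusted p = 0.125). The member that rose adjusted over the list alone was the malic enzyme Me1, at 1.03, chosen for mention after its value was seen. The male-labelled lines on their own gave no call for this list (adjusted p = 0.232).

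The other 27 of the 29 lists tested gave no camera call with the preset correlation over all genes and all 8 lines without covariates. Of these 27, 8 were called under some other setting. In 23 of the 29, limma called 0 members over all genes, and the counts at an unadjusted p under 0.05 are given with each list. Of all 22180 genes, 3127 had an unadjusted p under 0.05 and 58 were called. The list counts are to be read against these shares, and 0 called members is not in itself a result about a list. The test of change in either direction that fry also gives, again without comparing a list with other genes, was under the threshold in 17 of the 29 lists.

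Limma called no member of the hepatocyte lists over all genes. Above the median gene level lay 4 of 28 secreted proteins, 10 of 17 transcription factors and 5 of 19 amino acid and urea cycle genes. The same held for 3 of 24 drug and bile acid genes and 1 of 8 genes of gluconeogenesis and hepatocyte glycolysis. Of 28 secreted proteins 3 had an unadjusted p under 0.05, 0 passed over all genes and 1, Fga, rose adjusted over the list alone (0.54, SE 0.10). Fga had a low mean level of 3.59, against 5.66 for the median gene. Rbp4, which carries retinol, differed by -0.54 (SE 0.18, adjusted p = 0.235), with ICC2.7 at 5.43 and the other ICC lines at 6.06 to 6.11. The secreted protein list had a mean of -0.01 and a median of 0.00 (camera adjusted p = 0.927). Among 17 hepatocyte transcription factors 4 had an unadjusted p under 0.05 and 0 passed either way. The bile acid receptor Nr1h4 differed by 0.35 (adjusted p = 0.168) and Esrra by -0.26 (adjusted p = 0.216), and the list mean was -0.22 (camera adjusted p = 0.209, from 0.0413 to 0.861 over the settings). Amino acid and urea cycle genes, 19 measured, had 0 at an unadjusted p under 0.05 and 0 passing, with Arg1 at 0.25 and Cth at 0.84, a mean of 0.02, a median of -0.03 and a camera direction lower in ICC (adjusted p = 0.927). Drug and bile acid metabolism genes, 24 measured, had 1 at an unadjusted p under 0.05 and 0 passing, with Cyp2f2 at -0.21, Baat at -0.26 and a mean of -0.09 (camera adjusted p = 0.276). In the 8 genes of gluconeogenesis and hepatocyte glycolysis, 2 had an unadjusted p under 0.05 and 0 passed over all genes. Adjusted over the list alone 1 fell, the coactivator Ppargc1a (-1.73, SE 0.33, adjusted p over all genes 0.0769), while G6pc differed by 0.25; the list mean was -0.22 and the median 0.01 (camera adjusted p = 0.641).

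Over all genes and all 8 lines without covariates camera called none of the bile duct, epithelial and progenitor lists. Among 23 cholangiocyte markers 4 had an unadjusted p under 0.05 and 0 passed over all genes or adjusted over the list alone. Of the 23, 7 lay above the median gene level. Prom1 differed by -0.45 (adjusted p = 0.294), Cd24a by -0.68 (adjusted p = 0.303) and the list mean by -0.12 (camera adjusted p = 0.292). Of 25 genes of epithelial junctions and keratins, 5 had an unadjusted p under 0.05, 0 passed over all genes and 1 fell adjusted over the list alone, the tight junction gene Ocln (-1.80, SE 0.41). Cldn2, a claudin, differed by -2.51 (SE 0.75, adjusted p = 0.199), and the list mean was -0.39 (camera adjusted p = 0.114). Camera called this list lower in ICC among genes above the median level (adjusted p = 0.00552) and without ICC9, ICC10 or HCC4 (0.0137 to 0.0205). It also called it with sex and the missing direction in the model (0.0428) and with sex in the model without ICC9 (0.0443). With an estimated correlation its adjusted p was 0.861. Mesenchymal transition genes, 21 measured, had 3 at an unadjusted p under 0.05 and 0 passing, with S100a4 at 0.94, Itga5 at -0.66 and a list mean of 0.27 (camera adjusted p = 0.292, from 0.0413 in the male-labelled lines to 0.895 over the settings). Fetal liver and progenitor genes, 18 measured, had 4 at an unadjusted p under 0.05 and 0 passing, with Trim71 at 0.42, Sall4 at -0.29, a mean of 0.03, a median of -0.02 and a camera direction lower in ICC (adjusted p = 0.872). Of 22 pancreatic and intestinal lineage genes 5 had an unadjusted p under 0.05. Pdx1, the homeobox factor of pancreatic development, rose from 5.52 ± 0.06 in HCC to 6.39 ± 0.06 in ICC lines (SD, n = 4 each, adjusted p = 0.00948) and was the 1 member called over all genes. Adjusted over the list alone 1 rose and 2 fell, Gata4 (-0.93, adjusted p over all genes 0.054) and Onecut3 (-0.42), and the list mean was -0.06 (camera adjusted p = 0.325).

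Among signalling lists the Wnt and Hippo-YAP targets each held 1 gene that passed over all genes, and over all 8 lines without covariates camera called none of these lists. Notch pathway genes, 22 measured, had 3 at an unadjusted p under 0.05 and 0 passing, with Lfng at -1.09, Nrarp at -0.90 and a mean of -0.21 (camera adjusted p = 0.292). Of 19 Wnt pathway targets 3 had an unadjusted p under 0.05 and 1, Tbx3, fell over all genes and adjusted over the list alone, while Nkd1 differed by 0.45 and Ccnd1, cyclin D1, by 0.56. The list mean was 0.00 (camera adjusted p = 0.813). Of 22 Hippo-YAP targets 8 had an unadjusted p under 0.05 and 1, Gadd45b, fell over all genes, with 3 higher and 3 lower adjusted over the list alone. Ccn2, a matricellular protein, differed by -1.62 (SE 0.31, adjusted p = 0.0806) and Dlc1 by 0.76 (adjusted p = 0.0916), and the list mean was -0.25 (camera adjusted p = 0.241, from 0.023 in the female-labelled lines to 0.861 over the settings). In the TGF-beta pathway, 24 genes measured, 8 had an unadjusted p under 0.05, 0 passed over all genes, and 2 rose and 2 fell adjusted over the list alone, the inhibitor Smad6 (-0.70, adjusted p over all genes 0.0548) and the receptor Acvr1 (-0.49) among them; the mean was 0.03, the median -0.11 and the camera direction lower in ICC (adjusted p = 0.664). RAS-MAPK output genes, 21 measured, had 4 at an unadjusted p under 0.05, 0 passing over all genes and 1 lower adjusted over the list alone, Epha4 (-1.16, SE 0.19, adjusted p over all genes 0.0551). Dusp4 differed by -0.33, with ICC2.7 at 10.66 and the other ICC lines at 10.97 to 11.01, and the list mean was 0.06 (camera adjusted p = 0.378). MYC targets, 24 measured, had 2 at an unadjusted p under 0.05 and 0 passing, with Gnl3 at -0.28, Nop58 at 0.34 and a mean of 0.06 (camera adjusted p = 0.325, from 0.0183 in the male-labelled lines to 0.929 over the settings). The oncogenes of the vector, given gene by gene because only 2 were measured, had 0 at an unadjusted p under 0.05 and 0 passing. Whether the probe sets tell the vector's copy from the mouse gene was not examined. Nras measured 10.16 ± 0.05 in ICC and 10.11 ± 0.07 in HCC lines (adjusted p = 0.824), and Myc 8.52 ± 0.16 and 8.47 ± 0.43 (adjusted p = 0.934).

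With 1 probe set per gene camera called none of the lists of stress, death and immune signalling over all 8 lines without covariates. Of 17 p53 targets and cell cycle inhibitors 2 had an unadjusted p under 0.05, 0 passed over all genes, and adjusted over the list alone Cdkn2a rose (0.64, SE 0.15) and Pmaip1 fell (-0.71, SE 0.19, with HCC4 at 7.75 and the other HCC lines at 8.24 to 8.32). The list mean was -0.07 (camera adjusted p = 0.771). Necroptosis and death receptor genes, 21 measured, had 3 at an unadjusted p under 0.05, 0 passing over all genes and 1 higher adjusted over the list alone, Mlkl, the executor of necroptosis (0.82, SE 0.13, adjusted p over all genes 0.054). Tnfrsf10b differed by -0.29 and the list mean by 0.04 (camera adjusted p = 0.927). Among 29 cytokines and chemokines 4 had an unadjusted p under 0.05, 0 passed over all genes and 1, Il33, rose adjusted over the list alone (0.94, SE 0.16, adjusted p over all genes 0.0619). Il34 differed by 0.40, and the list had a mean of 0.06 and a median of -0.01 (camera adjusted p = 0.410). Interferon response genes, 26 measured, had 4 at an unadjusted p under 0.05, 0 passing over all genes and 1 higher adjusted over the list alone, Ifit1 (0.63). Ifi27 differed by 0.62 and the list mean by 0.02 (camera adjusted p = 0.891). NRF2 and glutathione genes, 18 measured, had 5 at an unadjusted p under 0.05, 0 passing over all genes, and 1 higher and 2 lower adjusted over the list alone, among them Gclc (0.46, with ICC2.9 at 9.62 and the other ICC lines at 9.24 to 9.29) and the transporter Abcc3 (-1.62); the list mean was 0.06 (camera adjusted p = 0.292). Immediate early and heat shock genes, 23 measured, had 5 at an unadjusted p under 0.05 and 0 passing, with Hspa1a at -0.73, Hsph1 at -0.64 and a list mean of -0.25 (camera adjusted p = 0.276). The mean of this list was 0.24 in female- and -0.74 in male-labelled lines, and over the settings its adjusted p ran from 0.00142 to 0.861. Glycolysis genes tied to proliferation, 13 measured, had 3 at an unadjusted p under 0.05 and 0 passing, with Pfkfb3 at -0.35, Hk2 at -0.30 and a mean of -0.18 (camera adjusted p = 0.0698, from 0.00488 to 0.861 over the settings). Camera called this list lower in ICC with probe set means (adjusted p = 0.0453), with sex in the model (0.0368) and in male-labelled lines (0.017). It also called it without ICC9 (0.0123), ICC10 (0.00488) or HCC4 (0.0322), with sex and the missing direction (0.0344) and without ICC9 with sex (0.0303). With an estimated correlation or with fry the list was not called.

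Over all 8 lines without covariates camera called none of the lists of endothelial, leukocyte, fibroblast and matrix genes. Of 18 endothelial markers 3 had an unadjusted p under 0.05 and 0 passed. The receptor Flt1 differed by 1.08 (adjusted p = 0.242), Tek by 0.24 and the list mean by 0.12 (camera adjusted p = 0.927). Of 19 leukocyte and macrophage markers 3 had an unadjusted p under 0.05, 0 passed over all genes and 1, Cd3e, fell adjusted over the list alone (-0.39, SE 0.08), from a level of 4.74 ± 0.10 in HCC lines, with ICC9 at 4.32 and each other ICC line at 4.36. Marco differed by -0.25 and the list mean by -0.10 (camera adjusted p = 0.629). Of 18 stellate cell and fibroblast markers 3 had an unadjusted p under 0.05 and 1, Col3a1, rose over all genes; adjusted over the list alone 2 rose, Col3a1 and Reln (0.34, SE 0.08), while Des differed by -0.87 and the list mean by 0.18 (camera adjusted p = 0.325, from 0.0344 in the male-labelled lines, with a mean of 0.55, to 0.936 over the settings). Extracellular matrix genes, 30 measured, had 7 at an unadjusted p under 0.05, 1 called over all genes, Col3a1 again, and 2 higher and 2 lower adjusted over the list alone. The collagenase Mmp13 differed by -3.08 (SE 0.59, adjusted p = 0.0798), Col6a2 by 0.98 (SE 0.23, adjusted p = 0.124) and the list mean by 0.16 (camera adjusted p = 0.325).

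**Figure D5:**
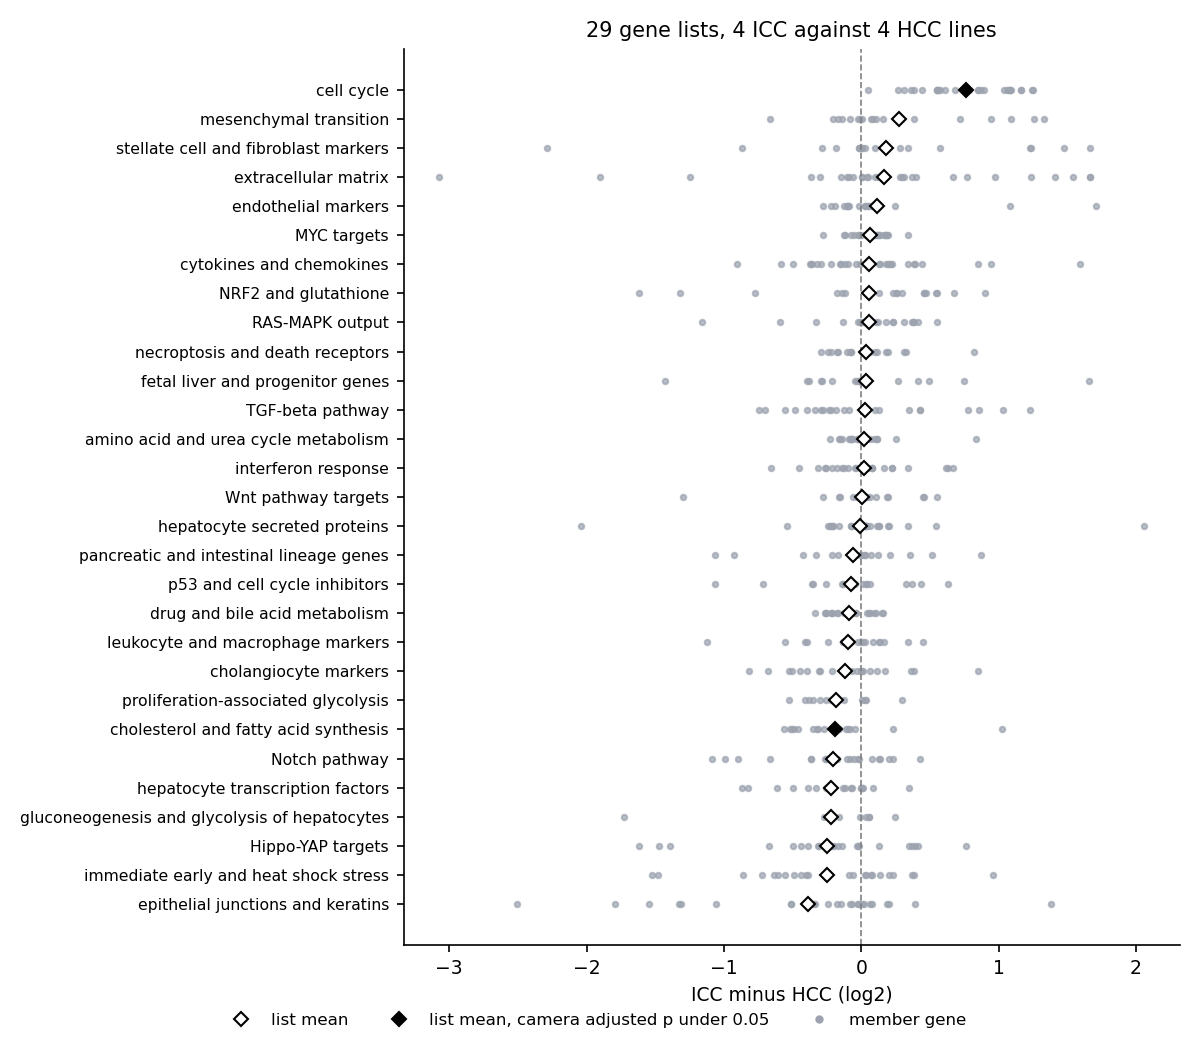
Log2 difference between ICC and HCC lines for 29 gene lists, 1 small point per member gene and 1 diamond for the list mean; filled diamonds mark lists with a camera adjusted p under 0.05 at the preset correlation. The filled diamonds are cell cycle (mean 0.77) and cholesterol and fatty acid synthesis (mean -0.19).

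Sex labels were checked with genes of the sex chromosomes and matched in all 8 lines. Xist, the RNA that silences the inactive X chromosome, measured 11.41 ± 0.14 in female- and 4.35 ± 0.26 in male-labelled lines (SD, n = 4 each, adjusted p = 2.54e-07). The Y-linked genes Uty (3.41 and 8.12, adjusted p = 5.06e-07), Kdm5d (3.77 and 7.94, adjusted p = 7.53e-05) and Eif2s3y (4.13 and 8.17, adjusted p = 0.000108) were higher in the male-labelled lines. In the list of sex-linked genes, 4 measured, limma called all 4 by sex and 0 by tumour type, with 0 of the 4 at an unadjusted p under 0.05 for type and a mean type difference of -0.05. With tumour type in the model 653 genes differed by sex, 325 higher in male- and 328 higher in female-labelled lines. Only 31 of them lay on X and 3 on Y, and 195 outside X and Y differed by at least 1 log2 unit. The autosomal genes with the smallest adjusted p were Bcat1, which starts the breakdown of branched-chain amino acids, at 7.25 in female- and 9.16 in male-labelled lines (adjusted p = 9.06e-05), and the chemokine gene Cxcl16, at 9.12 and 6.39 (adjusted p = 0.000108). The labels do not say whether lines of one type and sex share a source, so sex and source cannot be separated: 280 genes differed by sex with the missing direction in the model, 334 with the lines of one type and sex as a random block, and 6 with those lines averaged, where Bcat1 (adjusted p = 0.0848) and Cxcl16 (adjusted p = 0.0651) were not called. Without 1 line the count moved over 1.5 times for ICC9 (146), ICC10 (385), ICC2.7 (348), ICC2.9 (354), HCC2.1 (285) and HCC2.4 (294).

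Whether the difference between tumour types depends on the sex label was tested with an interaction term. Limma called 0 of 22180 genes (4467 at an unadjusted p under 0.05), which with 2 lines per type and sex does not show that there is no such dependence. Of the 58 genes that differed by type, 12 had an unadjusted interaction p under 0.05. This share is close to that over all genes, so the count is not a result about the 58. Serpinh1, for example, differed by 3.45 in female- and 5.30 in male-labelled lines, and Igfbp3 by -2.58 and -3.22. Without ICC9 the count was 238 and without ICC10 it was 10, and the term was not independent of the direction missing from the table (cosine 0.345).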

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

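The tests of each line as a weighted sum or mixture of the others, the models with the missing direction, the averaged fit by sex, the distances within a type and sex, the growth state test, the counts over other splits and the list tests for dependence on sex were chosen only after the result was seen. Leaving out 1 line and leaving out genes on X and Y were planned settings, set against the explanations after the result was seen. A line was singled out where its gap to the nearest of the other 3 lines of its type, divided by the range of the 4, passed the 95% limit of Dixon's test. Chance flags about 1 in 20 groups, and of 274 groups looked at 15 were singled out, where 13.7 would come by chance.

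Among genes the ratio of gap to range was 0.849 for Cd28 in ICC2.7 (6.00, other ICC lines 6.79 to 6.93), 0.889 for Tmem117 in ICC2.7 (6.38, others 6.62 to 6.65), 0.926 for Rbp4 in ICC2.7 (5.43, others 6.06 to 6.11), 0.886 for Dusp4 in ICC2.7 (10.66, others 10.97 to 11.01) and 0.889 for Vim in ICC2.7 (13.58, others 13.49 to 13.50). In ICC2.9 it was 0.9 for Nrcam (5.93, others 5.23 to 5.30), 0.88 for Hmgcs1 (9.62, others 9.84 to 9.87) and 0.868 for Gclc (9.62, others 9.24 to 9.29). In ICC9 it was 0.929 for Hnf4a (5.92, others 5.36 to 5.40) and 1 for Cd3e (4.32, each other line 4.36). Among HCC lines it was 0.926 for Akr1c18 in HCC1 (8.16, others 10.53 to 10.72), and in HCC4 0.864 for Gadd45b (8.86, others 8.42 to 8.48) and 0.86 for Pmaip1 (7.75, others 8.24 to 8.32). For list means it was 0.833 for the stellate cell and fibroblast markers in HCC1 (5.61, other HCC lines 5.39 to 5.43) and 0.847 for the oncogenes of the vector in HCC4 (8.94, others 9.36 to 9.43).

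In 4 lists the difference between ICC and HCC lines differed between female- and male-labelled lines by camera on the interaction term, with 2 lines per type and sex. Immediate early and heat shock genes had a mean difference of 0.24 in female- and -0.74 in male-labelled lines (adjusted p = 0.00292, 0.000237 to 0.0307 without 1 line, adjusted p = 0.623 with an estimated correlation). MYC targets had -0.06 and 0.19 (adjusted p = 0.0186, 0.0153 to 0.0593 without 1 line, lost without HCC1, adjusted p = 0.623 with an estimated correlation). Cell cycle genes had 0.58 and 0.95 (adjusted p = 0.0301, 1.07e-12 to 0.424 without 1 line, lost without ICC2.9 at 0.0855, HCC4 at 0.424 and HCC2.4 at 0.11, adjusted p = 0.691 with an estimated correlation). Leukocyte and macrophage markers had 0.10 and -0.30 (adjusted p = 0.0401, 0.0159 to 0.126 without 1 line, lost without ICC2.9 at 0.0821, HCC1 at 0.0593, HCC4 at 0.126 and HCC2.4 at 0.11, adjusted p = 0.623 with an estimated correlation). Without 1 line the lone line of its type and sex is assumed to vary like the others.

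The values of the 8 lines span 7 directions: each line is a weighted sum of the other 7, with a residual SD from 0.0037 (ICC9) to 0.0483 (HCC4), where rounding to 2 decimals alone gives 0.0037 and 0.0485. Mixed RNA and a close relation of ICC9 and ICC10 were set against the exactness of this sum. The best positive mixtures of the other lines left 0.136 (ICC9) or more for each line, and ICC9 and ICC10 differed with an SD of 0.211. Both values lie above rounding, but noise between arrays could also give them, so on their own they exclude neither explanation. Such noise would also keep mixed RNA or related lines from giving a sum exact to within rounding, as was found for each of the 8 lines. The exactness argues against both as the source of the sum. Whether RNA was mixed or ICC9 and ICC10 are related was not otherwise tested. With ICC9 at a weight of 1 and the other lines at their weights with the sign reversed, the weights sum to 0 within each type and each sex, which is what a covariate fitted beside type and sex and subtracted from the values before deposit would leave. Such a step may be the cause, as a hypothesis found and tested on the same values, and the labels name no such step. No biological explanation was tested.

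More genes differed by sex label (653) than by tumour type in the same model (428). Genes on X and Y do not account for this, since 619 of the 653 lie elsewhere, and neither does a degree of freedom counted too many, since with the missing direction 280 genes differed by sex and 119 by type. An animal or tumour shared by the 2 lines of one type and sex cannot be told apart from sex: pairs of one type and sex had a mean absolute difference of 0.195 against 0.296 for one type and different sex, but the labels do not give the source of the lines. Sex of the animals stays open as an untested biological explanation.

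Cell cycle genes had a mean difference of 0.77 between ICC and HCC lines (28 of 28 genes positive, adjusted p from 4.49e-25 to 0.861 over the settings), with ICC2.7 and ICC2.9 above all HCC lines and ICC9 and ICC10 below HCC1. An effect of 1 line is argued against by the smallest mean of 0.6512 without 1 line. Leaving out single lines does not test whether the pair ICC2.7 and ICC2.9, or another pair of one type and sex, carries the difference. The growth state of the cultures when RNA was taken cannot be told apart from tumour type, since no measure of it was used here and the highest HCC line, at 8.979, lies above the lowest ICC line. Tumour type stays open as an untested biological explanation.

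Other splits of the 8 lines into 4 and 4 were fitted in the same way. For type, 2 of 35 splits gave at least 58 genes, so chance is not excluded: the highest other, 246, was the split by sex, which points to a structure of the samples, and with sex in the model the type count was 428, or 119 with the missing direction as well. With the missing direction in the model 4 of 35 splits gave at least 12 genes (highest other 92), so chance is not excluded there either. For lists by type, without that direction in the model, 26 of 35 splits gave at least 2 (highest other 10), so chance is not excluded. For sex, 1 of 34 splits gave at least 653 genes (highest other 0) and 1 of 34 gave at least 280 with the missing direction (highest other 9). These counts do not exclude chance, because only 2 of the 34 splits keep the lines of one type and sex together, and with such lines averaged 6 genes differed by sex. For lists by sex 2 of 34 splits gave at least 9 (highest other 9), so chance is not excluded.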

How the results depend on the processing

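The models with the missing direction, the model without ICC9 with sex, the block and averaged fits by sex and the distances over unnamed probe sets were chosen after the result was seen, and all other settings were planned. No gene called by type (26 of the 101 named), list (2) or sex gene (6) changed sign under any setting. For the genes this was fixed in advance wherever lines were left out or averaged. In each of them all 4 lines of one group lay above all 4 of the other, so a constant sign is not evidence of robustness. All 26 stayed called with trend and robust settings, quantile normalization, centring, probe set means, sex as a covariate and the female-labelled lines, and 24 of the 24 present stayed called above the median level. Of the 26, 13 stayed with the male-labelled lines, 6 with the random block, 0 with averaged lines, 10 with the missing direction, 24 with sex and that direction, 12 without ICC9 with sex, and 2 to 23 without 1 line. All 26 also stayed called with array weights, whose fit did not converge; leaving that fit aside, adjusted p ran from 0.000389 to 0.371 for Olr1, from 0.000529 to 0.6 for Igfbp3, from 0.00301 to 0.867 for Serpinh1 and from 0.000189 to 0.6 for Akr1c18. For the 58 genes differing by type the count was 103 above the median level (fewer genes tested), 36 over all probe sets (more tested), 2278 with array weights, 428 with sex, 696 in female- and 200 in male-labelled lines, 6 with the random block (consensus correlation 0.398), 0 with averaged lines (limma, 1170 at an unadjusted p under 0.05), 12 with the missing direction, 119 with sex and that direction, 23 without ICC9 with sex, and 2 to 109 leaving out 1 line (ICC9 2, ICC10 64, ICC2.7 16, ICC2.9 28, HCC1 109, HCC4 91, HCC2.1 4, HCC2.4 5); the cause was not tested except where stated. With an absolute log2 difference of at least 2 in place of 1, 6 genes remained of 39. The 2 lists called became 7 in the male-labelled lines, 2 to 7 leaving out 1 line (ICC9 4, ICC10 7, HCC4 4), 4 with sex and the missing direction, 4 without ICC9 with sex, 0 with an estimated correlation and 0 with fry; the cause was not tested. Cell cycle adjusted p ran from 4.49e-25 to 0.861 and cholesterol synthesis from 0.000445 to 0.861. The 653 genes differing by sex became 2036 with array weights, 280 with the missing direction, 334 with the random block (consensus correlation 0.175), 6 with averaged lines, where Bcat1 and Cxcl16 were not called, and 146 to 917 leaving out 1 line (ICC9 146, ICC10 385, ICC2.7 348, ICC2.9 354, HCC2.1 285, HCC2.4 294, HCC4 917); the cause was not tested. The interaction count of 0 became 238 without ICC9 and 10 without ICC10 and stayed 0 without each other line, where a lone line is assumed to vary like the others; the cause was not tested. The difference in distance between and within types was 0.0256 to 0.0531 under its alternatives, against 0.0378, the lowest over probe sets with no gene name, where only ICC9 and ICC10 stayed nearest to the line of the same type and sex and the other 6 lines lay nearer to ICC9 or ICC10. No paired analysis was possible because the replicate numbers only follow the order of the samples and the labels give no link between lines of the 2 types. Signal over background was not assessed, and 4 arrays per type limit what can be called.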

Other observations

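The tests of lists by sex label, the model with the missing direction and the averaged fit were chosen only after the result was seen, and the genes named here were chosen after their values were seen. By sex label limma called 3 of 23 cholangiocyte markers and 2 of 25 genes of epithelial junctions and keratins, all higher in female-labelled lines, and 3 of 21 mesenchymal and 6 of 30 matrix genes, all higher in male-labelled lines. With the missing direction in the model 3 of the 3 cholangiocyte, 1 of the 2 epithelial, 2 of the 3 mesenchymal and 4 of the 6 matrix calls stayed, and with the lines of one type and sex averaged none stayed. Krt19, a keratin of bile duct cells, measured 8.55 ± 0.69 in female- and 6.36 ± 0.55 in male-labelled lines (log2, SD, n = 4 each, adjusted p = 0.00483), and Bicc1, an RNA-binding protein of tubular epithelia, 8.12 ± 0.44 and 6.28 ± 0.20 (adjusted p = 0.000693). The tight junction claudin Cldn6 measured 9.93 ± 0.38 and 5.98 ± 1.35 (adjusted p = 0.00233). In the other direction Mmp2, a gelatinase, measured 5.52 ± 0.39 and 9.86 ± 1.45 (adjusted p = 0.00483), Sparc 9.59 ± 0.42 and 10.84 ± 0.14 (adjusted p = 0.0111), and the matrix proteoglycan Bgn 7.05 ± 0.55 and 11.29 ± 1.94 (adjusted p = 0.0155). For each of these 6 genes all 4 lines of one sex lay above all 4 of the other, and averaging the lines of one type and sex ended each of these calls (adjusted p from 0.0933 for Krt19 to 0.314 for Sparc).

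Camera called 9 of 29 lists by sex label with the preset correlation, and all 9 calls were lost with an estimated correlation (smallest adjusted p = 0.143 with an estimated correlation). Higher in female-labelled lines were cholangiocyte markers (18 of 23 genes, mean male minus female -0.39, adjusted p = 2.68e-05), epithelial junctions and keratins (22 of 25, -0.61, adjusted p = 0.000261), proliferation-associated glycolysis (11 of 13, -0.31, adjusted p = 0.00118) and the Notch pathway (16 of 22, -0.22, adjusted p = 0.0135). Higher in male-labelled lines were cell cycle genes (28 of 28, 0.39, adjusted p = 3.79e-07), MYC targets (21 of 24, 0.17, adjusted p = 8.96e-05), extracellular matrix (19 of 30, 0.36, adjusted p = 0.00141), mesenchymal transition (17 of 21, 0.57, adjusted p = 0.00142) and stellate cell and fibroblast markers (12 of 18, 0.44, adjusted p = 0.0135). Only the stellate cell and fibroblast call was lost without 1 line, ICC2.9 (adjusted p = 0.0628). Another split of the lines also gave 9 lists, so chance is not excluded, and the source of the lines cannot be separated from their sex.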
